A study of Mus musculus with 10 samples.

How the data were processed

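Poly(A) RNA from the colon of DSS-treated mice was sequenced, per the labels' protocols, in 10 libraries, 5 labelled WT and 5 labelled Ldlr KO. The protocol text covers directional and non-directional libraries without saying which was used, so the strand of the reads is not given in the sources used here. Per the submitters' processing notes, FastQC 0.11.8, STAR 2.7.3a, RSEM 1.3.2 and DESeq2 1.36.0 were used, with the mouse build mm10; their roles and settings are not given in the sources used here.

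The authors deposited a table for each library with 55401 genes. Per the file headers it holds expected counts (estimated counts in which RSEM divides reads between transcripts and genes), TPM, FPKM, length and effective length. Over all libraries 5.9% of the deposited expected counts were not whole numbers. TPM and FPKM are RSEM measures that divide a count by effective length and scale it for sequencing depth. FPKM was not used here. Because RSEM shares reads among near-identical sequences, the level of a gene with close copies is an estimate, and because effective length follows the transcripts RSEM assigned, a TPM moves when that assignment moves even if the count does not.

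Gene identifiers were paired with symbols and positions through the GENCODE vM21 annotation of the GRCm38 assembly, the assembly behind mm10; 54349 identifiers matched with their version and 55141 without it. Expected counts were rounded to whole numbers. Library totals ran from 16.0 to 20.3 M rounded counts. At that depth a count of 1 is about 0.05 CPM, and the fitted standard errors and the SD between libraries carry both counting error and the spread between libraries. Intervals cover sampling error only.

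The only comparison the labels imply is Ldlr KO against WT. It was fitted with edgeR 4.0.16 in R 4.3.3 (TMM normalization, filterByExpr on the genotype, robust dispersion estimates, glmQLFit and glmQLFTest, two-sided), with an intercept and the genotype as terms, and a Benjamini-Hochberg adjusted p under 0.05 as the threshold over 16157 genes. The common biological coefficient of variation was 22.5%. CPM in the text uses TMM-scaled totals. Simulated counts were drawn from the means and totals of these libraries, with 50 genes changed at each fold among 15939 genes fitted. A further set of genes, which formed a test list, was also changed 1.5-fold. Of the 50 at each fold the test recovered 40% at 1.5-fold, 70% at 2-fold, 82% at 3-fold and 90% at 4-fold. Among all its 155 calls 8 were of unchanged genes. Each gene was drawn independently, without shared differences in tissue or sex between libraries, so this false share does not carry over to these data.

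Choices of test, gene lists and the naming rule were made before the data were examined. There were 48 gene lists, 21 of pathways and 27 of cell types or neighbouring tissues, with 601 members, of which 598 were found in the tables and 544 were tested. A list score is the mean log2 CPM (prior count 2) over the measured members, compared by an exact permutation test of the difference of means over all 252 arrangements, two-sided, with Benjamini-Hochberg adjustment over the 48 lists. The 44 lists with at least 5 measured members were also tested with camera of limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and with fry, which tests whether members move on balance in 1 direction and does not compare them with other genes. Library totals, genes detected, mitochondrial share and the share of the 10 most abundant genes were compared by exact permutation tests. Genes within 20 Mb of Ldlr were compared with all others by Fisher's exact test.

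Named genes were Ldlr; the 12 higher and 12 lower genes with the largest fitted fold change among those past the threshold with a mean of at least 1 CPM; in each list up to 4 measured members with the lowest p; and up to 6 genes past the threshold within 20 Mb of Ldlr, plus Nnt. The rule gave 212 genes with a test result, 99 of them past the threshold. The text gives a level or fold for 65 of the 212, and these were picked by hand after their values were seen; genes past the threshold that lost the call when a library was left out were mostly dropped, so the printed genes overstate the stability of the rule's genes. Stability is therefore counted over all 99. Marker genes of sex, position, pancreas and muscle that lie outside the rule were chosen after their values were seen.

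Alternatives were DESeq2 1.42.0, voom with quality weights, RLE factors, library totals alone, other count filters, RSEM effective lengths as offsets, the replicate number as a block, 1 surrogate variable from sva 3.50.0, other thresholds, and leaving out each library in turn. After the data were seen, fits were added with the 7 libraries with Xist reads, a term for Y-linked reads, the libraries with pancreas or muscle transcripts left out, and the distal position list score as a covariate. No pair of libraries of a group agreed within sampling noise, which does not exclude a shared animal. The lowest chi-square per degree of freedom was 7.42, for Ldlr KO replicates 4 and 5, and the next 14.6, for WT replicates 2 and 5. Isoform-level tables were not analysed here.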

Results

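RNA sequencing was carried out on colon tissue of mice that had drunk dextran sulfate sodium (DSS), a sulfated polymer that injures the colonic epithelium and brings on colitis. The drug was given at 3% for 5 days and the colon was taken on day 8, from animals 8 to 10 weeks old, as stated in the series design. There were 10 libraries, 5 labelled wild type (WT) and 5 labelled Ldlr KO, a line in which the low density lipoprotein receptor gene was targeted. Every animal received DSS, so the comparison was between genotypes within colitis, and no effect of DSS itself could be measured. The series title places it in a study of the receptor in intestinal inflammation. Library totals ran from 16.0 to 20.3 M counts (M, mega), 18.6 ± 1.53 M in WT and 17.7 ± 1.73 M in Ldlr KO (SD, n = 5 each; exact permutation test, two-sided, p = 0.444). The share of counts from mitochondrially encoded genes was 4.85 ± 0.362% in WT and 5.48 ± 0.86% in Ldlr KO (n = 5 each; exact permutation p = 0.159). Among the 4 library measures compared, the lowest Benjamini-Hochberg adjusted p of the exact permutation tests was 0.46. The series design speaks of mice, but no label says that each library came from a separate animal. The p-values therefore set group differences against the spread between these libraries, and would be too small if libraries shared an animal.

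Ldlr (ENSMUSG00000032193.9; mm10 chromosome 9, 21723483 to 21749919, plus strand) carried more counts in each of the 5 libraries labelled Ldlr KO than in any WT library. Its level was 176 ± 15.5 CPM (counts scaled to a common library total) in WT and 268 ± 28.5 CPM in Ldlr KO (SD, n = 5 each), a log2 fold change of 0.61 ± 0.09 (SE). Its adjusted p was 0.00256 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The deposited tables also gave an effective length of the gene in each library, RSEM's abundance-weighted mean over its transcripts of the effective length, which is shorter than the transcript itself. That length was 4197 ± 44.9 nt in WT and 1516 ± 9.08 nt in Ldlr KO (n = 5 each; exact permutation p = 0.00794, the smallest that the 252 arrangements allow). The log2 ratio of -1.47 was the largest in size among the 10445 genes with at least 10 CPM. In the reference annotation the gene has 7 transcripts; the longest has 18 exons and 4627 nt, and the shortest has 7 exons, 1739 nt and ends at 21738532, upstream of the last exons. Ldlr TPM, which divides by the effective length, was 54.7 ± 5.89 in WT and 214 ± 18.0 in Ldlr KO (n = 5 each; exact permutation p = 0.00794). The count by itself therefore gave no sign of a loss, and the genotype names below follow the labels.

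**Figure D1:**
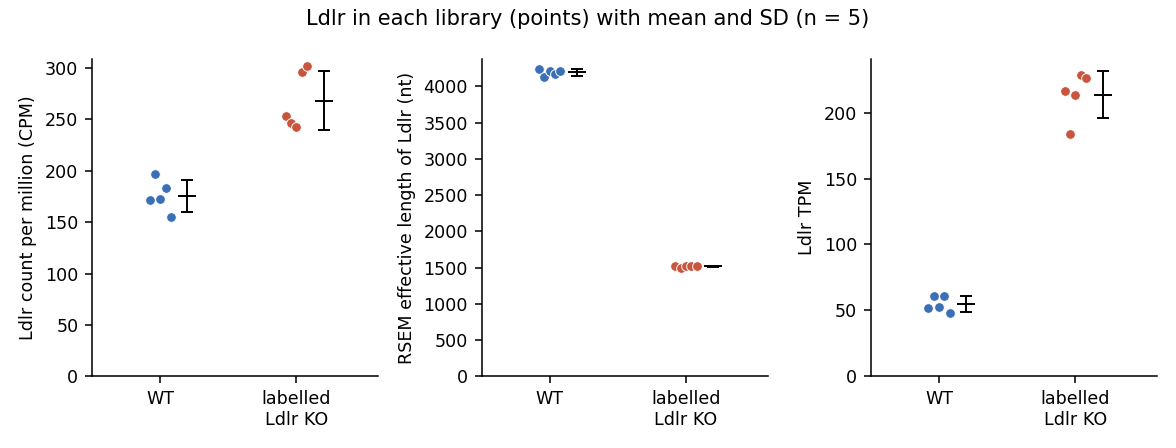
Ldlr in each library: CPM, RSEM effective length in nucleotides and TPM, with points for the 5 WT and the 5 Ldlr KO labelled libraries and black bars for the mean and SD. The count and the TPM are higher and the effective length is lower in all 5 Ldlr KO libraries, with no overlap between the groups.

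Colons labelled Ldlr KO carried less transcript of neutrophils, inflammatory cytokines and remodelled matrix, and more of goblet cells and cholesterol synthesis. As lists tested against all other genes, each of these 5 had an adjusted p = 0.272 with an estimated correlation (limma's camera), so the account rests on the genes and on the list scores. That shared value comes from the adjustment. The unadjusted p of the same test ran from 0.00712 for neutrophils to 0.0662 for cholesterol synthesis. S100a8, a calcium-binding protein abundant in neutrophils, was 9.06-fold lower, Lcn2, an iron-sequestering protein of inflamed epithelium and neutrophils, 11-fold lower, and the collagen cross-linking enzyme Lox 5.85-fold lower. In the other direction, Clca1, a secreted goblet cell protein, was 2.02-fold higher. Of 16157 genes tested, 1196 (7.4%) passed an adjusted p of 0.05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 364 higher and 832 lower in Ldlr KO. The number higher was less steady than the number lower: it was 219 with library totals alone and 230 with effective length offsets, where 837 and 648 were lower. An absolute log2 fold change of 1 or more was reached by 570 of them, 52 higher and 518 lower. The groups did not overlap for 1176 (7.28%) of the genes tested, against 0.794% by chance for 5 against 5. The first principal component of log2 CPM held 35.5% of the variance and separated the genotypes (exact permutation p = 0.00794). The number of genes past the threshold leaned on single libraries: it was 624, 622 and 728 without WT replicates 3, 4 and 5, 524 and 507 without Ldlr KO replicates 4 and 5, and 1929 without Ldlr KO replicate 1. Of the 99 genes past the threshold that the naming rule picked, 59 stayed past it without any 1 library and 40 lost the call without at least 1. The genes given below with a level or fold were chosen from these with their stability known, and 56 of 64 kept the call, so they are steadier than the rule's genes as a whole.

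**Figure D2:**
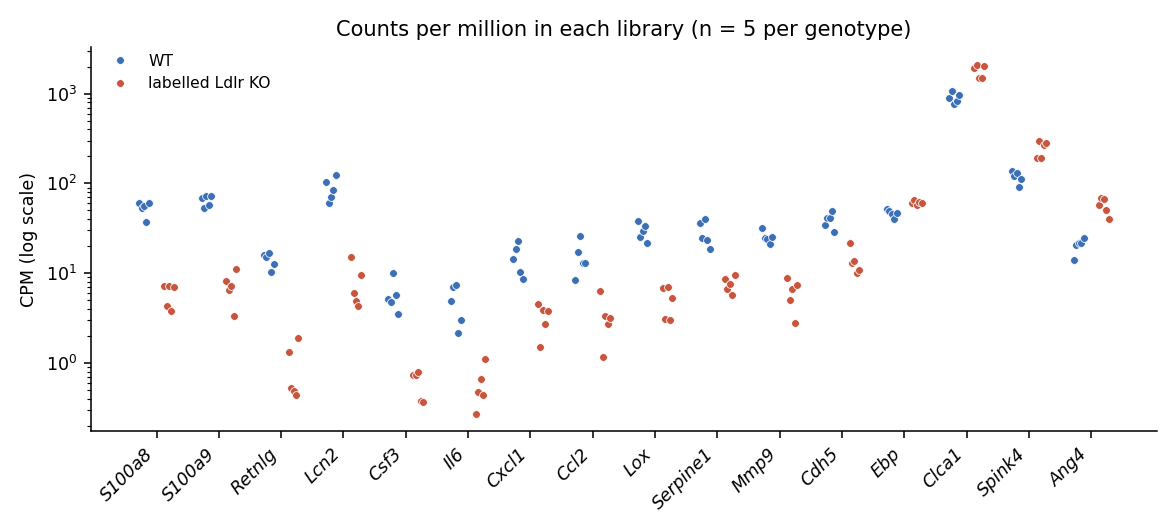
CPM (log axis) of 16 named genes in each of the 5 WT libraries and the 5 libraries labelled Ldlr KO, each point 1 library. From S100a8 to Cdh5 the WT libraries lie above the Ldlr KO libraries, and from Ebp to Ang4 they lie below, with no overlap in any of the 16.

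Neutrophil transcripts showed the deepest fall in mean score of any list. Of 11 measured neutrophil markers 9 fell and 0 rose (10 fell when adjusted over the list alone). S100a8 went from 53.4 ± 9.67 CPM in WT to 5.89 ± 1.73 CPM in Ldlr KO, with an adjusted p of 2.99e-05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and its partner S100a9 from 64.8 ± 9.05 to 7.26 ± 2.83 CPM (SD, n = 5 each). Retnlg, a resistin-like protein made by neutrophils, was 15-fold lower, and Mmp8, the neutrophil collagenase, 11.8-fold lower. The granule protein gene Ngp stood at 4.68 ± 2.79 CPM in WT and 0.0213 ± 0.0476 CPM in Ldlr KO, where Ldlr KO replicate 1 alone had reads. The mean log2 CPM over the neutrophil list was 4.0 ± 0.13 in WT and 1.44 ± 0.60 in Ldlr KO, and fell by 2.56 (exact permutation test, two-sided, adjusted p = 0.0254 over 48 lists). Against all other genes the list had an adjusted p = 0.272 with an estimated correlation. Without WT replicate 3 its score difference was -2.51 with an adjusted exact permutation p of 0.0586, as 0 of the 48 scores passed there. The unadjusted exact permutation p there was 0.00794 for the neutrophil, cytokine, chemokine, goblet cell and SREBP2 scores, the same as with all 10 libraries. For these scores that call was therefore lost through the adjustment over the 48 lists. Among the 12 named genes with the deepest fall, beyond those above, were Wfdc21 (14.6-fold), Ifitm6 (11.4-fold), Gbp10 (10.2-fold), the macrophage scavenger receptor Marco (9.65-fold), the chemokine Cxcl9 (9.61-fold), Csf3, which drives granulocyte production (9.55-fold), and the chitinase-like protein Chil3 (9.33-fold).

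Many but not all inflammatory cytokine and chemokine genes were lower in the libraries labelled Ldlr KO. Of 12 measured cytokines 7 fell and 0 rose; adjusted over the list alone, 9 fell and 1 rose. Il6 was 8.25-fold lower (log2 fold change -3.04 ± 0.45, SE) and Il11 5.27-fold lower (-2.40 ± 0.44), with adjusted p of 0.0026 and 0.0105 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of 18 chemokines 10 fell and 1 rose (13 and 1 when adjusted over the list alone); the riser was Ccl28, named after its value was seen. Lower were Cxcl1, a neutrophil attractant (4.5-fold), Ccl2, a monocyte attractant (4.66-fold), and Cxcl13, a B cell attractant (5.09-fold). The list scores fell by 1.57 for cytokines and by 1.45 for chemokines (exact permutation, adjusted p = 0.0254 each). Each had an adjusted p = 0.272 with an estimated correlation and an adjusted exact permutation p of 0.0586 without WT replicate 3. Saa3, an acute-phase protein, was 6.73-fold lower, while Ang4, an antimicrobial ribonuclease of secretory epithelial cells, was 2.76-fold higher. Across the 14 epithelial antimicrobial and acute-phase genes as a list, 1 rose and 2 fell (the same numbers adjusted over the list alone), and the score difference of -0.48 did not pass (exact permutation, adjusted p = 0.121).

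Matrix and remodelling genes moved almost as a block. Of 22 measured members 20 fell and 0 rose, over all genes and when adjusted over the list alone. Lox went from 29.5 ± 6.50 to 5.04 ± 1.93 CPM, its relative Loxl2 from 113 ± 9.09 to 43.7 ± 10.6 CPM, and Serpine1, the plasminogen activator inhibitor, from 28.8 ± 9.30 to 7.59 ± 1.5 CPM (SD, n = 5 each). Mmp9, a gelatinase, was 4.16-fold lower with an adjusted p of 0.00104 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The list score fell by 1.53 (exact permutation, adjusted p = 0.0254), and the list had an adjusted p = 0.272 with an estimated correlation. Fibroblast markers had 4 of 10 members lower and 0 higher (5 and 0 when adjusted over the list alone), including Pdgfra (1.99-fold) and Col6a2 (2.07-fold), and their score fell by 1.01 (adjusted exact permutation p = 0.0254; adjusted p = 0.272 with an estimated correlation). Blood endothelial markers had 7 of 9 members lower (8 when adjusted over the list alone), among them Cdh5, the endothelial cadherin (2.80-fold), Pecam1 (2.36-fold) and Eng (2.59-fold), with a score that fell by 1.04 (adjusted exact permutation p = 0.0254; adjusted p = 0.272 with an estimated correlation). Without WT replicate 3 the adjusted exact permutation p was 0.0586 for matrix, 0.0816 for fibroblasts and 0.0586 for blood endothelium. The matrix call was kept in 7 of the 10 fits with a library left out and was also lost without WT replicate 1 or 4. The fibroblast and endothelial calls were kept in 5 and lost without any 1 of the 5 WT libraries. Among 6 lymphatic endothelial markers only Pdpn, which fibroblasts also express, passed (2.37-fold lower), and the score difference of -0.54 did not (adjusted exact permutation p = 0.127). Smooth muscle markers had 0 of 10 members past the threshold and a score difference of 0.19 (adjusted exact permutation p = 0.381).

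Scores of monocytes and macrophages, T cells, cytotoxic genes and dendritic cells were lower. Few T cell, cytotoxic and dendritic genes passed the threshold one by one, and B cell genes did not. Of 15 monocyte and macrophage genes 6 fell (13 when adjusted over the list alone), among them Itgam, an integrin of myeloid cells (2.86-fold), and Ccr2, the receptor for Ccl2 (2.96-fold); the score fell by 1.09 (exact permutation, adjusted p = 0.0254; adjusted p = 0.272 with an estimated correlation). Of 13 T cell genes 3 fell (12 when adjusted over the list alone), including Foxp3, the regulatory T cell factor, which was low throughout at 2.18 ± 1.40 CPM in WT and 0.449 ± 0.181 CPM in Ldlr KO (SD, n = 5 each). The T cell score fell by 1.43 (exact permutation, adjusted p = 0.0254; adjusted p = 0.311 with an estimated correlation). The cytotoxic gene list had 1 of 5 members lower, Gzmb (2.64-fold; 2 lower when adjusted over the list alone), and a score that fell by 0.92. The dendritic cell score fell by 0.97 with 1 of 7 members lower and 5 when adjusted over the list alone (exact permutation, adjusted p = 0.0254 each; adjusted p = 0.272 with an estimated correlation for both). Without WT replicate 3 the adjusted exact permutation p was 0.0586 for the monocyte, T cell and cytotoxic scores and 0.0896 for dendritic cells. The monocyte and dendritic cell calls were kept in 5 of the 10 fits with a library left out and lost without any 1 of the 5 WT libraries. The T cell call was kept in 7 and the cytotoxic call in 6; both were also lost without Ldlr KO replicate 4 or 5, and the cytotoxic call without WT replicate 2. B cell genes had 0 of 10 members past the threshold, over all genes or over the list alone, with a score difference of -1.47 (exact permutation, adjusted p = 0.109). The interferon response had 6 of 27 members lower (18 when adjusted over the list alone), including the GTPase Ifi47 (2.19-fold), and a score difference of -0.67 that did not pass (exact permutation, adjusted p = 0.0635). MHC class II genes had 1 of 10 lower (9 when adjusted over the list alone) and a score that fell by 1.06 (exact permutation, adjusted p = 0.0477; adjusted p = 0.34 with an estimated correlation), a call that was kept in 1 of the 10 fits with a library left out, that without Ldlr KO replicate 1. Across those 10 fits the unadjusted exact permutation p for MHC class II was at most 0.0476. Red blood cell genes had 4 of 5 lower (5 when adjusted over the list alone), with Hbb-bs at 52.0 ± 13.8 CPM in WT and 23.9 ± 6.84 CPM in Ldlr KO. Hbb-bs shares reads with Hbb-bt, so the division between them is uncertain. The red blood cell score fell by 1.18 (exact permutation, adjusted p = 0.0254), and camera gave adjusted p = 0.272 with an estimated correlation. That score call was kept in 6 of the 10 fits with a library left out. It was lost without WT replicate 1 or 3 or Ldlr KO replicate 4 or 5, with an unadjusted exact permutation p of at most 0.0159 in any of the 10 fits.

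Some genes of cholesterol synthesis and of goblet cells were higher in Ldlr KO, by smaller factors, and most members of both lists did not pass. Of 23 measured targets of SREBP2, the transcription factor of sterol synthesis, 6 rose and 0 fell (8 and 0 when adjusted over the list alone), and 22 of the 23 had a log2 fold change above 0. Other lists also leaned up: 17 of 17 nuclear oxidative phosphorylation members were above 0 (median 0.22, against 0.27 for SREBP2). So were 10 of 10 goblet cell, 12 of 15 absorptive colonocyte and 14 of 17 tight junction members. Among enteroendocrine and tuft cell members it was 5 of 10 and 3 of 6. Whether a dilution of non-epithelial cells, weighed below for lower genes, raised these lists was not tested. Ebp, a sterol isomerase, was 1.31-fold higher and Acat2, the cytosolic thiolase that starts the pathway, 1.32-fold higher, with adjusted p of 0.00979 and 0.0146 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The SREBP2 list score was 6.11 ± 0.12 in WT and 6.37 ± 0.07 in Ldlr KO (SD, n = 5 each), a difference of 0.26 (exact permutation, adjusted p = 0.0254). The list had an adjusted p = 0.272 with an estimated correlation, and its score an adjusted exact permutation p of up to 0.0762, without Ldlr KO replicate 4; the score call was also lost without WT replicate 3 or Ldlr KO replicates 1 or 5. Of 18 LXR targets and cholesterol efflux genes 1 rose and 0 fell (the same over the list alone); it was Scd2, a fatty acid desaturase (1.76-fold), and the score difference was -0.09 (exact permutation, adjusted p = 0.515). The fatty acid uptake, synthesis and lipoprotein assembly list also had 1 member higher of 11, Acly (1.45-fold). Lipoprotein receptors and uptake genes had 2 of 14 members lower (7 lower and 1 higher when adjusted over the list alone), among them the scavenger receptor Msr1 (2.51-fold), and a score difference of -0.45 (exact permutation, adjusted p = 0.0635).

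Goblet cell genes rose in 3 of 10 measured members and fell in 0 (7 and 0 when adjusted over the list alone), and their score rose by 0.51 (exact permutation, adjusted p = 0.0254). The goblet cell list had an adjusted p = 0.272 with an estimated correlation, and its score an adjusted exact permutation p of 0.0586 without WT replicate 3. Clca1 went from 900.2 ± 113 to 1819 ± 287 CPM and Spink4, a secreted protease inhibitor, from 118 ± 18.0 to 245 ± 50.6 CPM (SD, n = 5 each). Fcgbp, another goblet cell gene past the threshold, lost the call without at least 1 library (adjusted p up to 0.102 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Absorptive colonocyte genes had 2 of 15 members higher and 0 lower (4 and 0 when adjusted over the list alone), with a score difference of 0.34 (exact permutation, adjusted p = 0.19). Nuclear genes of oxidative phosphorylation had 3 of 17 higher (4 when adjusted over the list alone) and a score difference of 0.24 (exact permutation, adjusted p = 0.109). Its members Ndufs1, Cox5a and Ndufb8 each lost the call without at least 1 library, with adjusted p of up to 0.0789, 0.115 and 0.124 by the same test. The unfolded protein response had 2 of 13 higher (6 when adjusted over the list alone), one of them Manf, a secreted chaperone (1.3-fold), with a score difference of 0.14 (exact permutation, adjusted p = 0.25). Ereg, an epidermal growth factor family ligand, was 3.30-fold lower and the only 1 of 7 regenerating epithelium genes to pass; Hmox1, heme oxygenase, was 1.83-fold lower. The lists for fatty acid oxidation, tight junctions, cell cycle, mitochondrially encoded genes, crypt stem cells, enteroendocrine cells, tuft cells, squamous epithelium and enteric neurons had 0 members past the threshold over all genes. The autophagy and lysosome score fell by 0.08 (exact permutation, adjusted p = 0.0254), with 2 of 13 members lower (3 when adjusted over the list alone), a call kept in 4 of the 10 fits with a library left out and lost without Ldlr KO replicate 4 or any 1 WT library. In the 10 fits the unadjusted exact permutation p of that score was at most 0.0238. Camera did not pass the autophagy and lysosome list at the preset correlation (adjusted p = 0.127) and gave adjusted p = 0.386 with an estimated correlation. For the glycolysis, inflammasome, immediate early, tuft cell and enteroendocrine lists the median, the mean and the direction of the list test differed in sign.

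The genes with the highest fold in Ldlr KO were of mixed kinds, and for 8 of the 12 the library lowest in position markers of the distal colon did not stand above WT. They were Fut9, a fucosyltransferase (9.03-fold), the cation channel gene Trpv3 (6.28-fold), the orphan nuclear receptor gene Esrrg (5.33-fold), Gsdmcl2 (5.12-fold), Rims4 (4.74-fold), the enolase gene Eno3 (4.65-fold), Gsdmc4 (4.60-fold), Cyp2c68 (4.16-fold), Hottip, a non-coding transcript at the end of the HoxA cluster (3.84-fold), Smpx (3.74-fold), Ctse (3.69-fold) and Pdzd7 (3.51-fold). Ldlr KO replicate 2 was the lowest of its group for all 12, and for 8 of the 12 it lay at or below the highest WT library. For Gsdmcl2, Gsdmc4, Smpx and Pdzd7 it lay above every WT library. The same library had 0.3 CPM of Hoxb13, a gene of the most distal colon, against 118 to 160 CPM in the other 4 Ldlr KO libraries and 13.5 to 58.7 CPM in WT. Hoxb13 itself did not pass (log2 fold change 1.83 ± 0.98, SE; adjusted p = 0.326 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Gsdmcl2, Gsdmc4, Smpx and Pdzd7 stayed past the threshold without any 1 library. The other 8 lost the call without at least 1, with adjusted p from the same test of up to 0.112 for Ctse, 0.108 for Cyp2c68, 0.0959 for Trpv3, 0.0949 for Hottip, 0.0922 for Eno3, 0.0605 for Rims4, 0.0585 for Esrrg and 0.052 for Fut9. Gsdmcl2 and Gsdmc4 belong to a cluster of near-identical copies on chromosome 15 whose reads are divided by estimation, and Hottip borders an oppositely oriented gene while the strand setting of the counting is not given, so these levels are uncertain.

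**Figure D3:**
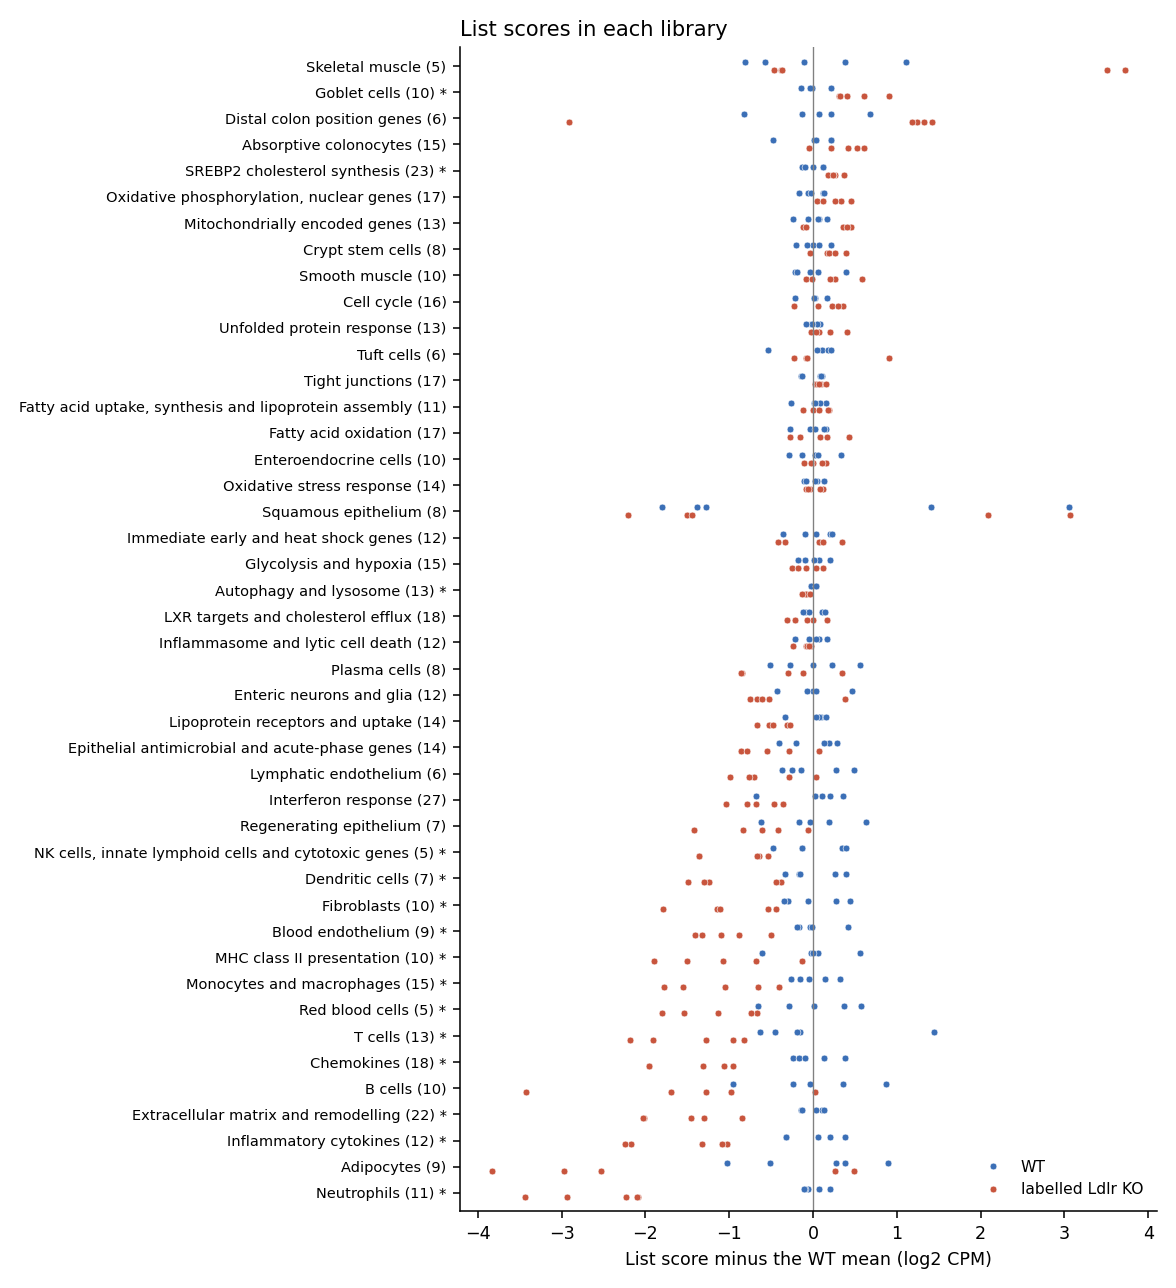
Mean log2 CPM over the measured members of each list with at least 5 (their number in brackets), less the WT mean, in each WT and Ldlr KO labelled library. Stars mark scores with an exact permutation adjusted p under 0.05 over 48 lists; the neutrophil list has the lowest Ldlr KO mean, at -2.56, and goblet cells and SREBP2 targets lie above WT.

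Over the 48 lists, 16 list scores passed, 2 higher and 14 lower in Ldlr KO (exact permutation, Benjamini-Hochberg adjusted). The count was 9 without WT replicate 1, 2 or 4, 10 without Ldlr KO replicate 4, and 0 without WT replicate 3, where 19 scores still had an unadjusted exact permutation p under 0.05. A test of each list against all other genes, limma's camera with a preset correlation of 0.01, passed 27 of 44 lists, 8 higher and 19 lower. With a correlation estimated from the data 0 of the 44 passed, 5 had an unadjusted p under 0.05, and limma's fry passed 19. For the matrix, neutrophil, cytokine, chemokine, SREBP2 and goblet cell lists camera gave adjusted p = 0.272 with an estimated correlation, and for the interferon list adjusted p = 0.34 with an estimated correlation.

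The libraries differed in sex-linked and neighbouring-tissue transcripts. Xist, which is transcribed from the inactive X chromosome, stood at 656 to 960 CPM in 7 libraries, and these had 0 reads of the 4 Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d. The other 3 libraries, WT replicate 1 and Ldlr KO replicates 4 and 5, carried Y-linked reads and at most 0.5 CPM of Xist. The series design describes male mice, which these 3 libraries match and the 7 with Xist reads do not. Within the 7 libraries with Xist reads, 4 WT and 3 Ldlr KO, 103 genes passed, 12 higher and 91 lower, and the 3 others were too few for a comparison of their own. In those 7 the rise of Ldlr, at a log2 fold change of 0.49, did not pass (adjusted p = 0.0731 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Pancreatic enzyme transcripts such as Amy2a5 reached 824 and 2297 CPM in WT replicates 3 and 4 and 237 CPM in Ldlr KO replicate 3, and 96 genes passed without these 3 libraries. Myh8, a skeletal muscle myosin, was found at 76.3 and 61.8 CPM in Ldlr KO replicates 4 and 5, and 168 genes passed without them. In each of these 3 smaller sets, all 1196 genes of the full comparison had the same direction, which the shared libraries favour. Adipoq, a fat cell hormone, was at 0 to 0.2 CPM in Ldlr KO replicates 1, 4 and 5, at 12.5 and 16.1 CPM in Ldlr KO replicates 2 and 3 and at 3.4 to 20.5 CPM in WT. The adipocyte score differed by -1.72 with 0 of 9 members past the threshold (exact permutation, adjusted p = 0.212). Krt5 and Krt14, keratins of squamous epithelium, were high in WT replicates 3 and 5 and Ldlr KO replicates 4 and 5.

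**Figure D4:**
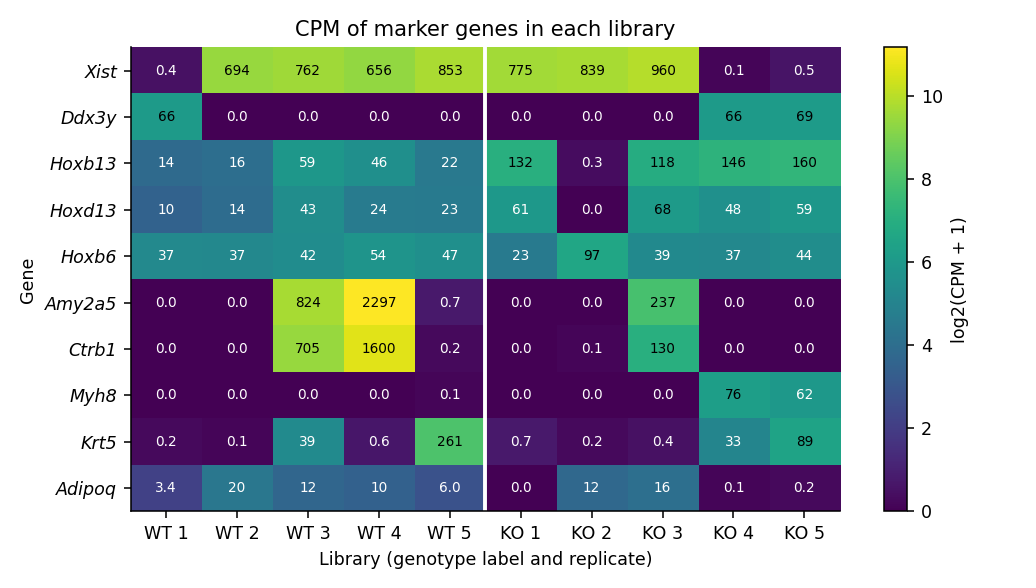
CPM of sex-linked, colon position, pancreas, muscle, squamous and fat marker genes in each library, with colour on a log2(CPM + 1) scale. Y-linked Ddx3y is found in WT 1, KO 4 and KO 5, Hoxb13 is near 0 in KO 2, and Amy2a5 marks WT 3, WT 4 and KO 3.

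Genes around Ldlr were examined because targeted alleles can carry flanking sequence of another strain. Within 20 Mb of Ldlr on chromosome 9, 18 of 196 genes passed (9.18%), against 1176 of 15949 elsewhere (7.37%), an odds ratio of 1.27 (95% interval 0.733 to 2.08; Fisher's exact test, two-sided, p = 0.335). The neighbours with the lowest p were lower in Ldlr KO: Mmp8, Mmp10, a stromelysin (5.90-fold), Icam1, an adhesion molecule that leukocytes bind (2.74-fold), the collagen gene Col5a3 (3.61-fold), the transcription factor gene Ets1 (3.09-fold) and the endothelial adhesion gene Esam (1.86-fold). Nnt, whose deletion marks the C57BL/6J substrain, is annotated under a pair of overlapping gene identifiers that share reads, so its level is uncertain and is not compared.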

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

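The gap test within groups of 5 was fixed beforehand and so were the counts over other splits of the libraries; the tests on Ldlr, on sex-linked reads, on position along the colon, on muscle and on dilution by other tissue were all chosen after the results were seen.

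Some values stood apart from the other 4 of their group: the gap to the nearest library, divided by the range of the group, passed 0.71, the 95% critical value for 5. This held in 23 of 254 groups of values, where chance gives about 12.7 (1 in 20), and the values are related to each other. Ldlr KO replicate 2 was lowest for the distal colon position score (gap 0.945), Hoxb13 (0.736), Rims4 (0.828) and Scd2 (0.792) and highest for the tuft cell score (0.855). Ldlr KO replicate 1 was highest for Ngp (1.0), where it alone had reads, for Cxcl13 (0.829), Hmox1 (0.720) and the enteric neuron and glia score (0.800). Ldlr KO replicate 3 was highest for Marco (0.736), and Ldlr KO replicate 4 was highest for Gbp10 (0.783) and lowest for the inflammasome score (0.737). WT replicate 1 was lowest for the tuft cell (0.781) and mast cell (0.739) scores. WT replicate 3 was highest for Esrrg (0.713), Eno3 (0.785) and the T cell score (0.773). WT replicate 4 was highest for Col6a2 (0.732) and the blood endothelium score (0.711) and lowest for the absorptive colonocyte score (0.714). WT replicate 5 was lowest for Mmp8 (0.776) and the lipoprotein receptor score (0.759) and highest for Gsdmc2 (0.783), a gene outside the naming rule that was chosen after its values were seen.

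Of 100 splits of the 10 libraries into 5 and 5, the real one included, 1 gave as many genes as the 1196 of the genotypes; the highest other split gave 39. A share of 1 in 100 is the smallest these splits can give, so an accidental split is an unlikely source of the number of genes. The count does not tell genotype from anything else that differed between the groups. For the camera lists 4 of the 100 splits gave 27 or more, and the highest other split also gave 27. A share of 4 in 100 is under 0.05, but other splits reached the same number of lists while calling 0 genes, so the number of lists by camera is weak evidence for the genotype.

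The neutrophil, cytokine and matrix genes had a median log2 fold change of -1.65. Within the 7 libraries with Xist reads it was -1.41, with a median SE of 0.35, so an uneven number of libraries with Y-linked reads is not the whole of it, although only 14 of 47 members passed among the fewer libraries. With the distal position score as a covariate the median was -1.72 (SE 0.26, 39 of 45 past). In that score 4 Ldlr KO libraries had 4.099 or more, against at most 3.59 in WT, and Ldlr KO replicate 2 lay below WT at 0.004. The covariate therefore rests on that library and does not separate position from genotype. Ldlr KO replicate 2 was still below every WT library in the neutrophil, cytokine and matrix scores, which a steady trend with position would not give. This is 1 library, so position along the colon stays open. The mean score of 13 other non-epithelial cell type lists also fell by 0.92. The neutrophil, cytokine and matrix scores less that mean differed by -1.64, -0.65 and -0.61 (exact permutation p = 0.00794, 0.0238 and 0.0159). These 3 lists were chosen after they were seen to fall, which favours such a difference. Within the 13, adipocyte, B cell and T cell scores differed by -1.72, -1.47 and -1.43, about as far as cytokines and matrix, and smooth muscle by 0.19. The neutrophil score fell further than any of the 13, which argues against an even dilution of non-epithelial cells as its whole cause. For cytokine and matrix genes dilution stays open, and for neutrophil genes as a part. A lower inflammatory response in mice labelled Ldlr KO is a hypothesis that these tests leave open, and so are differences in DSS intake, housing or collection time, which the labels do not give. The clock genes Nr1d1, Dbp and Nfil3, chosen after their values were seen, separated the groups, while Arntl and Npas2 overlapped. Nr1d2 and Tef, chosen in the same way, were higher in Ldlr KO and past the threshold in all 10 fits with a library left out. Collection time is therefore not set aside.

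The Ldlr count was higher in the libraries labelled Ldlr KO. Single swapped libraries are argued against by the effective length, for which 0 libraries lay in the range of the other group, and an exchange of both whole groups by its direction, since the libraries labelled WT had 4197 nt, near the full-length transcripts, and those labelled Ldlr KO 1516 nt. The SREBP2 list had a median log2 fold change of 0.27 against 0.61 ± 0.09 (SE) for Ldlr, and 0 of 23 members reached it. Members differed in size, with Tm7sf2 at 0.50 ± 0.12 (SE), so a median does not settle whether a shared rise of sterol synthesis genes played a part. The effective length of Ldlr changed by -1.47 on the log2 scale, and no other of 10445 genes changed as much. That may reflect reads that end early in the gene, as a disrupted allele would give, but read coverage along the gene was not available, so the allele itself was not examined.

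Among the 12 higher genes with the largest fold, Ldlr KO replicate 2, the library lowest in the distal position score, was the lowest of its group for 12 of 12, and WT replicate 3, the highest of WT in that score, was the highest WT library for 9. With that score as a covariate the median log2 fold change was 1.75, against 2.21 without it (SE 0.26, 12 past). The 4 other Ldlr KO libraries lay above every WT library for all 12 genes and also in that score (4.099 or more against at most 3.59). The covariate therefore does not separate position from genotype. For Gsdmcl2, Gsdmc4, Smpx and Pdzd7 Ldlr KO replicate 2 lay above every WT library although its score was lower than theirs, which a steady rise with position would not give. For the other 8 it lay at or below the highest WT library, so position stays open there as the whole or a part of the cause. Without the 2 libraries highest in skeletal muscle genes the median was 1.91 (SE 0.51) and 3 of the 12 passed with fewer libraries, so muscle is not the whole of it.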

How the results depend on the processing

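The fits on the 7 libraries with Xist reads, with a term for Y-linked reads, without the libraries with muscle or pancreas transcripts and with the distal position score were added after the data were seen; the other alternatives were planned.

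The number of genes past the threshold, 1196, ran from 507 without Ldlr KO replicate 5 to 1929 without Ldlr KO replicate 1 when 1 library was left out. It was 1985 at an adjusted p under 0.10, 570 at an absolute log2 fold change of at least 1, 1990 with DESeq2 and 2296 with voom. Among the added fits it was 103 in the 7 libraries with Xist reads, 168 without the 2 libraries with muscle transcripts, 96 without the 3 with pancreas transcripts, each with fewer libraries, and 2102 with the distal position score, where the cause was not tested. RLE factors, library totals, other count filters, effective length offsets, the replicate block, 1 surrogate variable, the term for Y-linked reads and removal of genes near Ldlr gave 878 to 1210. Of these the number higher, 364 in the full comparison, was 219 with library totals, 230 with effective length offsets and 210 with the replicate block, and the number lower, 832, was 837, 648 and 792. The genes were not all the same ones. Of the 1196, 810 also passed with the replicate block, 821 with effective length offsets, 884 with the Y-linked term and 964 with 1 surrogate variable. With the other settings of this group 937 to 1180 did. Library totals shifted the median gene by -0.06 on the log2 scale, the largest shift of the scalings.

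Ldlr ran from 0.57 to 0.66 with 1 library left out (adjusted p from 0.00169 to 0.00998 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment) and was 0.49 in the 7 libraries with Xist reads, where it did not pass with fewer libraries. Effective length offsets gave 2.08 (adjusted p = 4.14e-07), because they divide by the shorter length RSEM gave the gene in Ldlr KO; the other fits gave 0.50 to 0.67.

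Of 99 genes past the threshold that the naming rule picked, 59 kept the call in all 10 fits with a library left out, 20 kept it in every fit, and 0 reversed. The report gives a level or fold for 64 of the 99, of which 56 kept the call in those 10 fits; of the other 35, 3 did. The 64 were chosen with this known. The 40 that lost it include Fdps, Tm7sf2, Stat1, Gbp5, Il33, H2-DMa, Ndufs1, Cox5a, Hspa5, Car4, Fcgbp, Csf1r, Icos, Dcn, Ckm and Alas2. Among the 113 not past the threshold 19 reversed in some fit; Hoxb13, the only one with a level in the report, went to -0.0576 with the distal position score, the covariate it belongs to.

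Camera passed 27 lists, 25 to 29 with 1 library left out, and 0 with an estimated correlation (5 at an unadjusted p under 0.05), where limma's fry passed 19. Directions coded as 1 for higher and -1 for lower reversed in 58 of 924 comparisons over 11 lists. Of these lists only skeletal muscle had passed; it went to -1 in the 7 libraries with Xist reads and without the 2 libraries with muscle transcripts. The other 10 had not passed. Fatty acid uptake, fatty acid oxidation, glycolysis, inflammasome and oxidative stress went from 1 to -1, and antimicrobial, immediate early, enteroendocrine, tuft and squamous lists from -1 to 1, in at least 1 fit each; the cause was not tested.

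List scores past the threshold, 16 in all libraries, ran from 0 without WT replicate 3 to 17 without Ldlr KO replicate 1. The difference in total counts ran from -1.48 to -0.405 M, in detected genes from -105 to 105, in mitochondrial share from 0.449 to 0.871 percentage points and in the share of the top 10 genes from 0.348 to 0.865 points; none passed. The odds ratio of genes near Ldlr ran from 1.14 to 1.61 with 1 library left out.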

Other observations

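The circadian genes below were chosen after their values were seen and lie outside the naming rule, and no explanation was tested for them. Nr1d1 and Dbp, outputs of the circadian clock, had log2 fold changes of 1.12 ± 0.12 and 1.05 ± 0.13 (SE) in the libraries labelled Ldlr KO, with adjusted p of 0.000464 and 0.00104 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The clock genes Nr1d2 and Tef ran from 0.37 to 0.45 and from 0.34 to 0.42 with 1 library left out. Their adjusted p by the same test was at most 0.0176 and 0.0351 in those fits. Nfil3, which Nr1d1 represses, was at -1.55 ± 0.14, and the core clock gene Arntl at -0.13 did not pass (adjusted p = 0.677). The clock gene Npas2 overlapped between the groups, at 8.8 to 15.1 CPM in WT and 12.7 to 18.4 CPM in Ldlr KO. The hour of tissue collection is not given in the labels, so whether the groups were collected at different times stays open.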
